A study of Rattus norvegicus with 9 samples.

How the data were processed

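The series holds 9 one-colour (Cy3) Agilent rat gene expression arrays of total RNA from brain tissue of male Sprague Dawley rats, in 3 groups of 3 arrays. Per the labels, the 3 groups are sham-operated rats, rats with middle cerebral artery occlusion (MCAO) given saline vehicle, and MCAO rats given salidroside at 50 mg per kg. Injections were made once a day for 6 days, the first of them 1 h after reperfusion. Each array was used as 1 replicate, since the labels give 3 animals per group. Replicates carry the numbers that the labels give them within each group.

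Per the file headers, the authors made the array files with Agilent Feature Extraction 11.0.1.1 (protocol GE1_1100_Jul11), and the signal columns hold fluorescence intensity on a linear scale, background-subtracted and detrended within each array but not normalized between arrays. The design of the array was built on the rat genome assembly rn4. The deposited value table holds log2 values of 19477 probes for the same 9 arrays. Its columns share a maximum of 17.91 and have medians from 8.691 to 8.706, so it looks quantile-normalized, and it is not centred per gene. Each of its columns correlates with the log2 signal of its own array at an r of at least 0.99967. The column with the mean pixel signal of each spot was not used here.

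Analysis was done in R 4.3.3 with limma 3.58.1. Each array had 44254 spots, of which 42877 were not controls and represented 30367 probes. The processed signal was put on the log2 scale and each array's 75th percentile was subtracted. Spots marked as non-uniform or population outliers were left out, and spots of 1 probe were averaged. A probe was tested if it was well above background on every array of at least 1 group, by the majority of its spots, which left 25576 probes. Probe annotations were matched to gene symbols through transcript accessions, with a table built on the assembly GRCr8 that was used for names only. This named 18005 probes, and 12362 kept the accession or the probe name. No genomic positions are given, since the array and that table use different assemblies. For each name the probe with the highest mean log2 signal was kept, which gave 22783 features, 13276 with a gene symbol and 9507 without. Of these, 61 lacked a value on at least 1 array. Where several tested probes of a named gene disagreed in sign, their range is given.

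All 9 arrays were fitted in 1 linear model of 3 groups (lmFit, contrasts, eBayes), with 6 residual and 2.49 prior degrees of freedom. The contrasts were vehicle minus sham, salidroside minus vehicle, salidroside minus sham, and the mean of both MCAO groups minus sham. A feature was called at a Benjamini-Hochberg adjusted p under 0.05. Values of single genes are log2 changes with the standard error of the fit, and group values are means with the standard deviation over 3 arrays. The number of arrays limits their precision. Of 200 features changed in simulated data with the spread of these arrays, 35.8% of those set to a log2 change of 1, 86.6% of those set to 2 and 100% of those set to 3 were recovered for vehicle against sham. For salidroside against vehicle these were 17.9%, 86.6% and 100%. There were 10 and 13 false calls. These shares hold for data with that many changed features, since fewer changes make the adjusted threshold stricter. They do not carry over to salidroside against vehicle on the real arrays, where Egr2 (log2 change 3.84) and Arc (3.40) were not called.

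Gene lists, 18 of pathways and 19 of cell types or brain regions, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 37 lists of a comparison. An estimated correlation and fry were run beside it. In simulated data a list shifted by a log2 of 1 was called in both comparisons tested, and 0 of the other lists were. That 0 does not carry over to the real arrays. There, other splits of the same arrays called up to 17 lists for vehicle against sham and 20 for salidroside against vehicle. The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule takes, for vehicle against sham and salidroside against vehicle, the 6 largest called rises and falls whose arrays do not overlap between groups, the 4 smallest p-values of a direction without a call, up to 4 members of each list with the smallest p-values, the 4 early growth response genes, and Gfap, Hmox1, Fos, Arc and Rbfox3. For salidroside against sham it takes the 4 largest called changes in each direction. Rbfox3 had no named probe among the tested features.

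A scan identifier in the file headers sorts the arrays into 4 sets. Arrays that share it were taken to lie on 1 slide. Slide 1 held salidroside replicates 2 and 3 and vehicle replicates 1 and 3, slide 3 held salidroside replicate 1 and vehicle replicate 2, slide 2 held sham replicates 1 and 2, and slide 4, scanned on a second day, held sham replicate 3. No slide holds both sham and MCAO arrays, so comparisons with sham were rerun with slide as a random block only, and salidroside against vehicle with slide as a fixed block and within slides. The replicate numbers do not pair salidroside and vehicle arrays: deviations from the group means of arrays with the same number correlated across features at r of -0.11, -0.0639 and 0.0709. The first number in the sample titles does pair them, with r of 0.356, 0.466 and 0.354, each the highest for its salidroside array. Its meaning is not given, and the pairs lie within slides, so values with this number as a block are given beside the counts and list calls they change.

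Other settings were quantile and median scaling, the deposited value table, limma's normexp background correction with an offset of 50, no filter, probes well above background on all 9 arrays, the mean over probes, every probe, only the groups compared, a trend with robust estimation, array weights, an adjusted p under 0.1, an unadjusted p under 0.05 with a log2 change of at least 1, blocks for replicate number, slide, scan day and title number, and leaving out each array in turn. The closing section gives their effects. Control spots and spots marked as outliers were left out of all tests.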

Results

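Gene expression was measured on 9 arrays of rat brain, 3 from sham-operated rats, 3 from rats with middle cerebral artery occlusion (MCAO) and reperfusion given vehicle, and 3 from MCAO rats given salidroside, a glycoside found in Rhodiola roots. MCAO blocks the artery that feeds much of the cortex and striatum and is a standard model of stroke. On 8 arrays, 81.97% to 88.53% of probes were well above background, and the 75th percentile of the processed signal lay between 950.1 and 2340. Sham replicate 3, scanned on a second day, was dimmer, with 65.63% of probes well above background and a 75th percentile of 495.5. The median signal was 15.7% to 17.2% of the 75th percentile on the 4 arrays of slide 1, all from MCAO rats, and 13.2% to 14.4% on the 5 arrays of the other slides. Changes are relative to each array's 75th percentile, on which scale the median of all 22783 features differed by 0.099 between vehicle and sham, 0.049 between salidroside and vehicle and 0.117 between salidroside and sham (log2).

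The comparison of vehicle-treated MCAO rats with sham rats asks what ischemia and the days after it changed. Several of the genes that neurons switch on with activity fell after MCAO. Arc, which acts at active synapses, fell by 3.22 on the log2 scale, or 9.3-fold (SE 0.427, limma adjusted p = 0.01). Egr2 fell by 3.19 (SE 0.422, adjusted p = 0.00978), Egr4 by 3.18 (SE 0.463, adjusted p = 0.0143), Egr1 by 1.28 (SE 0.255, adjusted p = 0.0417) and the orphan nuclear receptor Nr4a1 by 2.31 (SE 0.303, adjusted p = 0.00957). For each of these genes all 3 vehicle arrays lay below all 3 sham arrays. The neuropeptide gene Cort had the largest fall among the genes named by the rule, 10.7-fold (log2 -3.42, SE 0.384, adjusted p = 0.005). Fos, the classical immediate early gene, had a log2 change of -1.59 (adjusted p = 0.051).

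Of the 4 early growth response genes, transcription factors induced by activity, 3 fell, and the same 3 passed adjusted over the list alone. The list median was -2.23 (camera adjusted p = 0.00156, adjusted p = 0.354 with an estimated correlation). Egr3 had a log2 change of 0.33 (adjusted p = 0.497), with probes from -0.23 to 0.33. As far as it is remembered, this family is a focus of the study's own publication, so its count is not independent evidence of a direction. Of 22 other immediate early genes, 3 fell, Arc, Nr4a1 and Junb, and 6 were lower adjusted over the list alone (median -0.70, camera adjusted p = 8.28e-06, adjusted p = 0.354 with an estimated correlation).

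The list of cholesterol synthesis genes was called lower. Of 16 measured, 15 had a negative change, 7 fell and 12 were lower adjusted over the list alone, with a median of -0.84 (camera adjusted p = 2.89e-11, adjusted p = 0.0913 with an estimated correlation). Hmgcs1 fell by 1.19 (SE 0.143, adjusted p = 0.00637) and Msmo1 by 1.18 (SE 0.175, adjusted p = 0.0155).

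Synaptic and neuronal lists were called lower. Glutamatergic synapse genes had a median of -0.34 with 1 of 21 past the test, Stx1a at -1.15 (camera adjusted p = 4.94e-05, adjusted p = 0.359 with an estimated correlation), and 2 passed adjusted over the list alone. Voltage-gated channels had a median of -0.45 with 0 of 17 past the limma test over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0137, adjusted p = 0.354 with an estimated correlation). Interneuron and GABAergic genes had a median of -0.15, with 1 of 15 past the test and 3 adjusted over the list alone, the neuropeptide Sst at -1.31 (camera adjusted p = 0.0148, adjusted p = 0.354 with an estimated correlation). Pan-neuronal markers had a median of -0.10, with Thy1 falling by 0.99 and 2 of 9 lower adjusted over the list alone (camera adjusted p = 0.04, adjusted p = 0.409 with an estimated correlation). Markers of cortical projection neurons had a median of -0.79, all 6 negative and Lamp5 past the test at -1.82, also the 1 gene that passed adjusted over the list alone (camera adjusted p = 0.00259, adjusted p = 0.359 with an estimated correlation). Striatal markers had a median of -0.75 with 0 of 13 past the limma test and 1 adjusted over the list alone (camera adjusted p = 0.00183, adjusted p = 0.491 with an estimated correlation). Sham replicate 1 stood 1.32 above the sham mean for the striatal list, and without it the median was -0.222 (adjusted p = 0.398) and the call was lost. Medians moved most with single arrays for channels (-0.222 without vehicle replicate 1, -0.171 without vehicle replicate 3), interneuron genes (-0.0971 without sham replicate 1, -0.0449 and -0.315 without vehicle replicates 1 and 2), pan-neuronal genes (-0.213 without sham replicate 1, -0.167 without sham replicate 2 or 3, -0.254 without vehicle replicate 2) and cortical markers (-1.19 without vehicle replicate 1). Leaving out vehicle replicate 3 ended the calls of channels, interneuron and pan-neuronal genes, as did sham replicate 1 for interneuron genes and sham replicates 2 and 3 and vehicle replicate 1 for pan-neuronal genes. Calls were also lost under quantile normalization, the deposited value table and probes above background on all 9 arrays for interneuron and pan-neuronal genes, with array weights for interneuron genes and striatal markers, with the replicate number as a block for pan-neuronal genes (adjusted p = 0.0658) and under the deposited value table for channels. Erythrocyte genes had a median of -1.15, and the globin Hbb fell by 1.26 (SE 0.252, adjusted p = 0.0433), with 2 of 4 lower adjusted over the list alone (camera adjusted p = 0.00417, adjusted p = 0.354 with an estimated correlation).

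Lists of reactive astrocyte, complement and macrophage genes were called higher at the preset correlation, though few members passed over all genes. Of 10 reactive astrocyte genes 3 rose, Steap4 by 2.21, the copper carrier Cp by 2.28 and the adhesion receptor Cd44 by 1.65, and 6 were higher adjusted over the list alone (median 1.59, camera adjusted p = 0.00417, adjusted p = 0.411 with an estimated correlation). The probes of Cd44 disagreed, from -0.79 to 1.65. Gfap had a log2 change of 1.54 (SE 0.539, adjusted p = 0.137). All 15 complement genes had a positive change, with C1qc past the test at 2.00 (SE 0.372, adjusted p = 0.0356) and 12 higher adjusted over the list alone (median 1.48, camera adjusted p = 9.54e-06, adjusted p = 0.411 with an estimated correlation). All 8 macrophage genes had a positive change, and the scavenger receptor Cd163 rose by 2.79 (SE 0.454, adjusted p = 0.0215) and Cd14 by 1.82 (SE 0.318, adjusted p = 0.0297), with 5 higher adjusted over the list alone (median 1.15, camera adjusted p = 0.0014, adjusted p = 0.359 with an estimated correlation). Under normexp correction, where the median of all features was -0.139, the macrophage median was 0.367 and the list stayed called (camera adjusted p = 0.00477). Phagocytosis and lysosome genes had a median of 0.70, with 0 of 20 past the limma test and 3 adjusted over the list alone (camera adjusted p = 0.000409, adjusted p = 0.557 with an estimated correlation). Extracellular matrix genes had a median of 0.70, with the protease inhibitor Timp1 rising by 2.19 and 6 of 17 higher adjusted over the list alone (camera adjusted p = 0.00257, adjusted p = 0.567 with an estimated correlation), and the call was lost without vehicle replicate 3 (median 0.276).

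Of 17 antioxidant genes 3 rose, the metallothioneins Mt1 by 2.42 and Mt2A by 2.02 and Nqo1 by 0.79, while Gclm fell by 2.33. Adjusted over the list alone, 4 were higher and 1 lower (median 0.30, camera adjusted p = 0.0479, adjusted p = 0.354 with an estimated correlation). Cell division genes had a median of 0.40 with 0 of 20 past the limma test, over all genes or adjusted over the list alone (camera adjusted p = 0.0469, adjusted p = 0.708 with an estimated correlation). Leaving out vehicle replicate 3 or any of several other arrays ended the calls of both lists, sham replicates 2 and 3, salidroside replicate 1 and vehicle replicate 1 for antioxidant genes and sham replicates 1, 2 and 3 for cell division. The cell division median was 0.0592 without vehicle replicate 3 and 0.626 without vehicle replicate 2, and its call was also lost with slide as a random block and under quantile normalization. The antioxidant call was also lost under median scaling (median 0.141, adjusted p = 0.0541) and with the replicate number as a block (adjusted p = 0.0504). The 20 lists that were not called included choroid plexus, with the largest median of them (1.39, camera adjusted p = 0.192), microglia (median 0.76, camera adjusted p = 0.0548), neutrophils (0.90, 0.0696), cytokines and chemokines (0.54, 0.0704), antigen presentation (0.46, 0.105), apoptosis (0.34, 0.381) and hypoxia (-0.0094, 0.661), although the hypoxia-induced peptide Adm rose by 1.55 (SE 0.294, adjusted p = 0.0372). Other large called rises were Lrrc34 by 2.84, Akap14 by 2.71, Cyp2b3 by 2.57 with probes from 0.241 to 2.57, and Calml4 by 2.51, and other large falls were Atad2 by 2.65 and Gclm. Akap14 was above background on no sham array, which puts its rise at a bound of at least 3.07-fold.

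In all, limma called 592 of 22783 features between vehicle and sham, 234 higher and 358 lower, and 5436 had an unadjusted p under 0.05. Arrays of both groups did not overlap for 28.8% of features, where chance gives 10%. MCAO and sham arrays shared no slide, so differences between slides cannot be told apart from those of MCAO, and with slide as a random block 279 were called. The count was 114 without sham replicate 3, 132 without vehicle replicate 3, 170 without sham replicate 2 and 295 and 305 without vehicle replicates 1 and 2. It was 310 and 346 without salidroside replicates 2 and 3, whose spread enters the fit, and 1071 without salidroside replicate 1. Few rises stayed called in some settings. Rises and falls numbered 15 and 99 without sham replicate 3 and 20 and 112 without vehicle replicate 3. They numbered 0 and 13 under normexp correction, but 604 and 467 without salidroside replicate 1. Vehicle replicate 2, the 1 vehicle array off slide 1, differed from the sham mean in the direction of the group for 591 of the 591 called features with a value on it, although it helped to select them.

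**Figure D1:**
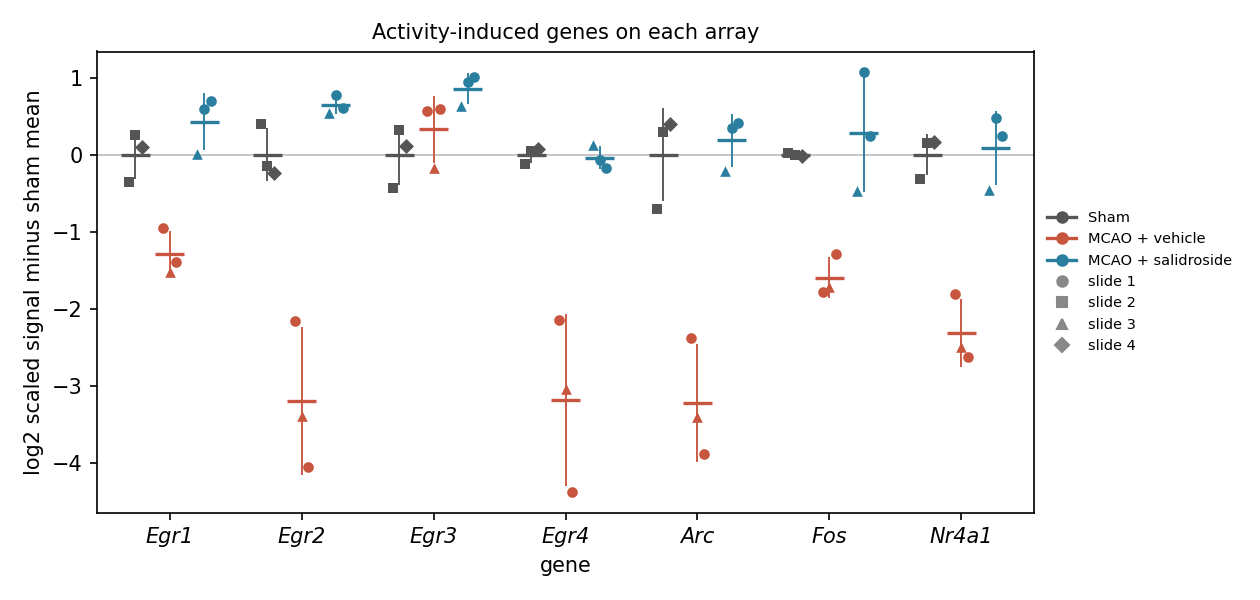
Log2 scaled signal minus the sham mean for 7 activity-induced genes on each of the 9 arrays, with group means as bars, standard deviations as vertical lines (n = 3) and slides as symbols. Vehicle arrays lie below the other 6 arrays for all of the genes shown except Egr3. For these genes the salidroside mean lies nearer to sham than the vehicle mean does, while for Egr3 both MCAO means lie above sham. Averaged over the 4 early growth response genes, the salidroside arrays lie above sham, at 0.326 to 0.559 against -0.129 to 0.116.

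Whether salidroside changed gene expression in ischemic brain is the question of the series. Between salidroside and vehicle limma called 3 features. Slc6a5, a glycine transporter of inhibitory nerve endings, fell by 1.92 (SE 0.167, adjusted p = 0.025), although its probes ranged from -1.92 to 0.035. Crisp3, a secreted cysteine-rich protein, fell by 1.83 (SE 0.179, adjusted p = 0.0355), but was at -0.0311 under normexp correction and lost its call in 13 of 16 settings, as Slc6a5 did in 12. The unnamed Ensembl transcript ENSRNOT00000026303 was 2.29 higher (adjusted p = 0.025) and is given because the count is small. For each of the 3 the salidroside and vehicle arrays did not overlap. All 3 were also called between vehicle and sham, in the opposite direction: Slc6a5 at 1.306 (adjusted p = 0.00844), Crisp3 at 1.805 (adjusted p = 0.00304) and ENSRNOT00000026303 at -2.182 (adjusted p = 0.00234), which the shared vehicle arrays favour.

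The named genes with the smallest p-values among those higher with salidroside did not pass. They were Egr2 (log2 3.84, SE 0.422, adjusted p = 0.0661), Hmgcs1 (1.24, SE 0.143, adjusted p = 0.0767), Cort (3.20, SE 0.384, adjusted p = 0.0851) and Arc (3.40, SE 0.427, adjusted p = 0.0854). All 4 are genes that fell after MCAO, and their values on the 3 salidroside arrays did not overlap with those on the 3 vehicle arrays. Egr2 stood at 0.84 ± 0.117 with salidroside, -2.99 ± 0.957 with vehicle and 0.20 ± 0.342 in sham (scaled log2, SD, n = 3). Within slide 1 its difference was 3.79 and within slide 3 it was 3.93, and for Arc these were 3.50 and 3.20.

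As lists, activity-induced and cholesterol genes were called higher with salidroside. The early growth response family had a median of 2.43 (camera adjusted p = 1.15e-09, adjusted p = 0.0533 with an estimated correlation), with 0 of 4 members past the limma test over all genes and 3 adjusted over the list alone. That count is not independent evidence either. Other immediate early genes had a median of 0.99 (0.656 without salidroside replicate 2), 20 of 22 positive, with 8 higher adjusted over the list alone (camera adjusted p = 8.16e-14, adjusted p = 0.0983 with an estimated correlation). Nr4a1 was among them at 2.4 (adjusted p = 0.0854), as was Fos at 1.87 (adjusted p = 0.269). All 16 cholesterol synthesis genes were positive, 10 of them higher adjusted over the list alone, with a median of 0.72 (camera adjusted p = 4.13e-21). It was the 1 list whose call held with an estimated correlation (adjusted p = 0.0178). Cyp51 had a log2 change of 1.11 and Msmo1 of 1.02 (adjusted p = 0.166 and 0.208).

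Lists of synapses, channels and cortical neurons were also called higher. Glutamatergic synapse genes had a median of 0.39, 19 of 21 positive and 1 higher adjusted over the list alone (camera adjusted p = 8.44e-06, adjusted p = 0.319 with an estimated correlation). For voltage-gated channels the median was 0.32, with 1 of 17 higher adjusted over the list alone (camera adjusted p = 0.000611, adjusted p = 0.151 with an estimated correlation). The calls of both lists were lost under normexp correction, where their medians were 0.666 and 0.511 and that of all features was 0.541. Cortical projection neuron markers had a median of 0.86, all 6 positive and Lamp5 highest at 1.76, with 1 higher adjusted over the list alone (camera adjusted p = 5.76e-05, adjusted p = 0.192 with an estimated correlation). Pan-neuronal markers had a median of 0.19 and were not called (camera adjusted p = 0.0865). Erythrocyte genes had a median of 1.35, Alas2 at 1.52 and Hbb at 1.18, with 3 of 4 higher adjusted over the list alone (camera adjusted p = 2.75e-06, adjusted p = 0.0533 with an estimated correlation).

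Lists of reactive astrocyte, complement, macrophage, phagocytosis, extracellular matrix and antioxidant genes were called lower with salidroside. Reactive astrocyte genes had a median of -0.95, with 3 of 10 lower adjusted over the list alone, among them Cp at -1.90 and Cd44 at -1.54 with probes from -1.54 to 1.30 (camera adjusted p = 8.44e-06, adjusted p = 0.198 with an estimated correlation). Their median was -0.442 without salidroside replicate 1, -1.52 and -0.566 without vehicle replicates 2 and 3 and -0.0318 under normexp correction. Complement genes had a median of -0.75, 13 of 15 negative and 0 past limma adjusted over the list alone, with C1qc at -1.27 (camera adjusted p = 4.8e-07, adjusted p = 0.321 with an estimated correlation). Their median was -1.26 without salidroside replicate 3, -0.462 without vehicle replicate 3 and -0.166 under normexp correction. Macrophage genes had a median of -0.91, with Cd163 at -2.07 (0.352 under normexp correction) and 4 of 8 lower adjusted over the list alone (camera adjusted p = 8.44e-06, adjusted p = 0.192 with an estimated correlation). Their median was -0.579 without vehicle replicate 3. Under normexp correction it was 0.185, where the median of all features was 0.541, and the call was lost (camera adjusted p = 0.163). Phagocytosis genes had a median of -0.42 (camera adjusted p = 9.24e-06, adjusted p = 0.341 with an estimated correlation), and 0 of 20 passed adjusted over the list alone. Their median was -0.14 and -0.743 without salidroside replicates 1 and 3 and -0.646 and -0.137 without vehicle replicates 2 and 3. Extracellular matrix genes had a median of -0.35, with 3 of 17 lower adjusted over the list alone, among them Dcn at -1.30 and Sparc at -1.22 (camera adjusted p = 2.75e-06, adjusted p = 0.321 with an estimated correlation). Their median was -0.625 without salidroside replicate 3 and -0.628, -0.662 and -0.157 without vehicle replicates 1, 2 and 3. Antioxidant genes had a median of -0.11 (-0.183 without vehicle replicate 2), with 3 of 17 lower adjusted over the list alone, Mt1 at -1.95, Mt2A at -1.60 and Nqo1 at -0.66 (camera adjusted p = 0.00172, adjusted p = 0.0983 with an estimated correlation). Cytokines and chemokines (median 0.10, camera adjusted p = 0.493) and antigen presentation (0.087, 0.728) were not called. With single arrays left out their medians changed sign, from -0.128 to 0.236 and from -0.221 to 0.343. Other immune and glial lists not called were neutrophils (-0.238, camera adjusted p = 0.493), T and NK cells (0.22, 0.493), B cells (0.213, 0.663) and oligodendrocytes (0.117, 0.814).

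The weakest calls were microglia (median -0.47, camera adjusted p = 0.011, adjusted p = 0.396 with an estimated correlation), meningeal fibroblasts (-0.39, camera adjusted p = 0.0168, adjusted p = 0.33 with an estimated correlation) and astrocytes (-0.16, camera adjusted p = 0.0363, adjusted p = 0.341 with an estimated correlation). Each of these 3 lost its call without any of 3 arrays: salidroside replicates 1 and 2 or vehicle replicate 3 for microglia, salidroside replicate 2 or vehicle replicates 2 and 3 for meningeal fibroblasts, and salidroside replicates 1 and 3 or vehicle replicate 2 for astrocytes. The medians were -0.244 and -0.762 without salidroside replicates 1 and 3 and -0.747 and -0.243 without vehicle replicates 2 and 3 for microglia, -0.155 without salidroside replicate 2 for meningeal fibroblasts and -0.007 without salidroside replicate 1 for astrocytes. Under normexp correction, where the median of all features was 0.541, the microglia median was 0.0777 and the list stayed called lower (camera adjusted p = 0.0134). The meningeal fibroblast call was also lost under the deposited value table. The astrocyte call was also lost with a number in the sample titles that pairs the arrays as a block (adjusted p = 0.0556), within slide 1 (adjusted p = 0.265), under median scaling and with array weights. Of the 9 microglial genes 8 were negative, among them P2ry12 at -0.86, and the receptor Cx3cr1 was the 1 positive gene at 1.08. The other 21 lists, not called, had medians from -0.62 for choroid plexus to 0.22 for T and NK cells. The choroid plexus median was -0.0681 without vehicle replicate 3. Apoptosis genes were called with slide as a block (median -0.129, camera adjusted p = 0.0497). Within slide 1, apoptosis (-0.169, camera adjusted p = 0.025) and oligodendrocyte genes (0.5, 0.0314) were called.

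**Figure D2:**
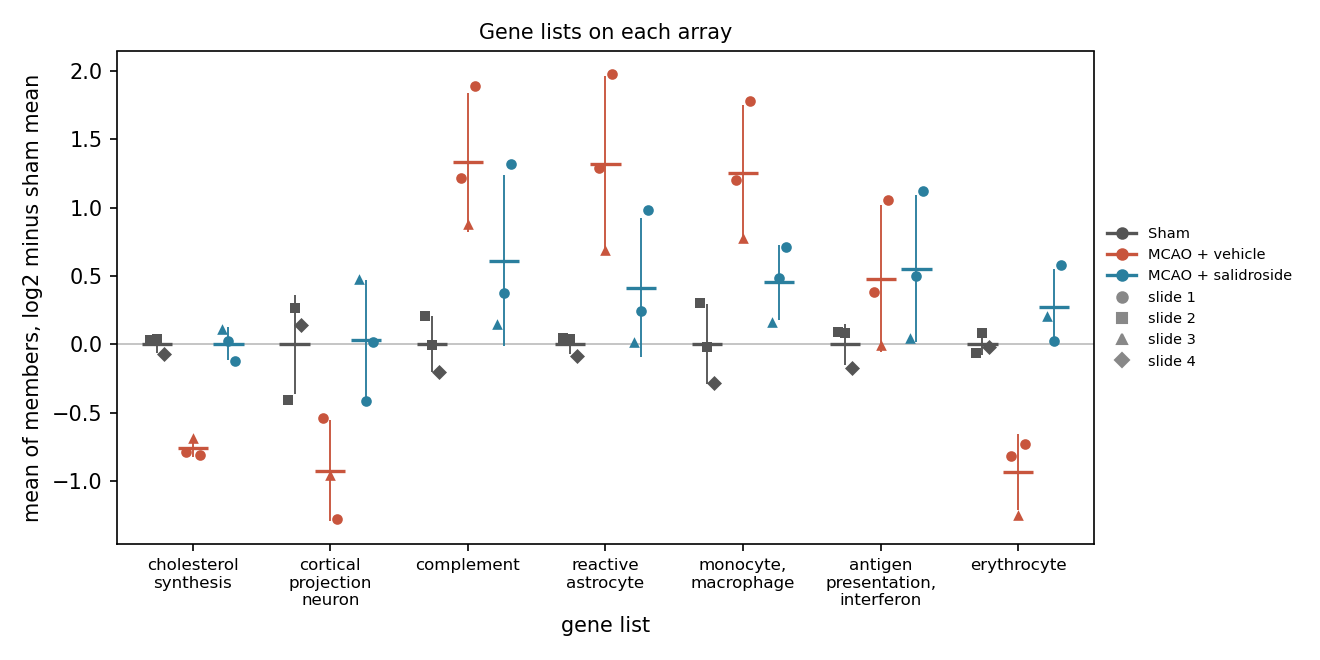
Mean log2 signal minus the sham mean over the measured members of 7 gene lists on each array, with group means as bars, standard deviations as vertical lines (n = 3) and slides as symbols. Cholesterol synthesis genes lie between -0.81 and -0.68 on the vehicle arrays and between -0.12 and 0.12 on the salidroside arrays.

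The 3 calls between salidroside and vehicle were kept under quantile and median scaling, the deposited value table, every probe, a trend with robust estimation and array weights. They were lost under normexp correction, without a filter and with only the 2 groups compared. With limma, 0 features were called with slide or with that title number as a block in the 6 MCAO arrays, and 0 within slide 1. In these fits 2093, 2203 and 1376 had an unadjusted p under 0.05. The 6 arrays without a block also gave 0 calls, with 1171 at an unadjusted p under 0.05, so the loss cannot be put down to the blocks. With slide as a block Slc6a5 stayed at -1.92 and Crisp3 at -1.83, as the groups are balanced over slides, and within slides 1 and 3 they were at -1.70 and -2.36 and at -2.03 and -1.43. The count was 8 without vehicle replicate 1 and 0 without any of the other 8 arrays, against 1351 features at an unadjusted p under 0.05 with all 9. For 11.9% of features the arrays of both groups did not overlap, where chance gives 10%. All 16 called lists had the same sign within slide 1 (2 arrays per group) and within slide 3 (1 per group), as with complement at -0.82 and -0.77, reactive astrocytes at -1.06 and -0.44 and cholesterol synthesis at 0.77 and 0.82. The change over all arrays is made up of these within-slide changes, and the lists were called on it, so the shared sign is largely built in. List calls need care at this size, since camera called 20 lists in another split of the same 6 arrays.

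Salidroside and sham were compared to see how far treated ischemic brain lay from sham. Limma called 267 features, 54 higher and 213 lower, and 3341 had an unadjusted p under 0.05. The largest called rises were Cyp2b3 at 2.63 (SE 0.487, adjusted p = 0.0463), Ston1 at 2.42 (SE 0.437, adjusted p = 0.0437), the olfactory receptor Or14j5e at 2.41 (SE 0.337, adjusted p = 0.014) and the corticotropin-releasing hormone receptor Crhr2 at 2.34 (SE 0.384, adjusted p = 0.0304). All 4 were dim, above background on 1 or 2 of the 3 sham arrays. The largest called falls were the catenin-family gene Arvcf at -2.04 (SE 0.204, adjusted p = 0.00281), the transcriptional regulator Id3 at -1.84 (SE 0.17, adjusted p = 0.0021), Gapdh-ps1 at -1.83 (SE 0.188, adjusted p = 0.00329) and Snx15 at -1.69 (SE 0.163, adjusted p = 0.00258). Only 47 of the 267 called features had a gene symbol. Of the lists called after MCAO, medians with salidroside against sham were 0.03 for cholesterol synthesis, 0.10 for other immediate early genes, -0.01 for cortical projection neurons, 0.536 for the early growth response family, 0.58 for complement, 0.47 for reactive astrocytes and 0.603 for macrophages, none of them called. The 1 list called was that of striatal markers, at -0.60 (camera adjusted p = 0.00957, adjusted p = 0.921 with an estimated correlation). Its call was lost without salidroside replicate 3 or sham replicate 1, under quantile normalization and with slide as a random block. The count of features was 90 and 99 without salidroside replicates 3 and 2, 98 without sham replicate 3, 162 and 170 without vehicle replicates 3 and 1, and 1031 without salidroside replicate 1, and 184 with slide as a random block.

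Of the features called in either direction between vehicle and sham, 45 of the 234 higher ones and 189 of the 358 lower ones were called the same way between salidroside and sham. Independent lists of these sizes would share 0.555 and 3.35, although both comparisons use the same sham arrays, which raises the overlap by an amount that was not measured. Probes without an accession made up 109 of the 189 shared falls, 153 of the 358 falls with vehicle and 122 of the 213 with salidroside. For the mean of both MCAO groups against sham, limma called 756 features, 371 higher and 385 lower, with 5154 at an unadjusted p under 0.05. Of 3227 probes without an accession 193 (5.98%) were lower, against 76 of 13276 named genes (0.572%). The count of 756 became 345 with slide as a random block, 145 without sham replicate 3, 242 and 273 without salidroside replicates 3 and 2, 250 and 345 without vehicle replicates 3 and 1, 411 without sham replicate 1 and 2061 without salidroside replicate 1. With only the 2 MCAO arrays of slide 3 against the 3 sham arrays, limma called 0, with 2069 at an unadjusted p under 0.05.

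Changes with salidroside ran against changes with ischemia. Across the 22783 features, which are not independent replicates, the log2 change of salidroside minus vehicle correlated with that of vehicle minus sham at r = -0.558. Both differences hold the vehicle arrays with opposite sign, and simulated groups without any effect gave -0.501 (from -0.521 to -0.479), and with an ischemia effect and no drug effect -0.27. The simulations took the groups as independent and left out the pairing of salidroside and vehicle arrays by title number, which makes the value without a drug effect less negative. The covariance was -0.115 against a simulated -0.0511. Of the 592 features called between vehicle and sham, 72.1% changed in the opposite direction with salidroside, against 66.8% (64% to 68.9%) in simulations with ischemia and no drug effect. All these simulations drew features independently, while genes varied together on the arrays (estimated correlation 0.63 for complement). They also set the ischemia effect to the estimated change of both MCAO groups. The simulated ranges are therefore too narrow to decide whether the observed values differ from them. Without salidroside replicate 1, r was -0.311, for which no simulation was run. That array correlated with the sham arrays at a mean of 0.9863 and with the other salidroside arrays at 0.9829. Of all features called higher with vehicle, 79.5% were lower with salidroside than with vehicle (median -0.477), and of all called lower 67.3% were higher with salidroside than with vehicle (median 0.149). This was 87.7% (median 0.534) for the 106 named genes and 58.7% (median 0.0528) for the unnamed features, for which no separate simulation was run. All 13 lists called both between vehicle and sham and between salidroside and vehicle had opposite signs in these comparisons, which the shared vehicle arrays favour.

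**Figure D3:**
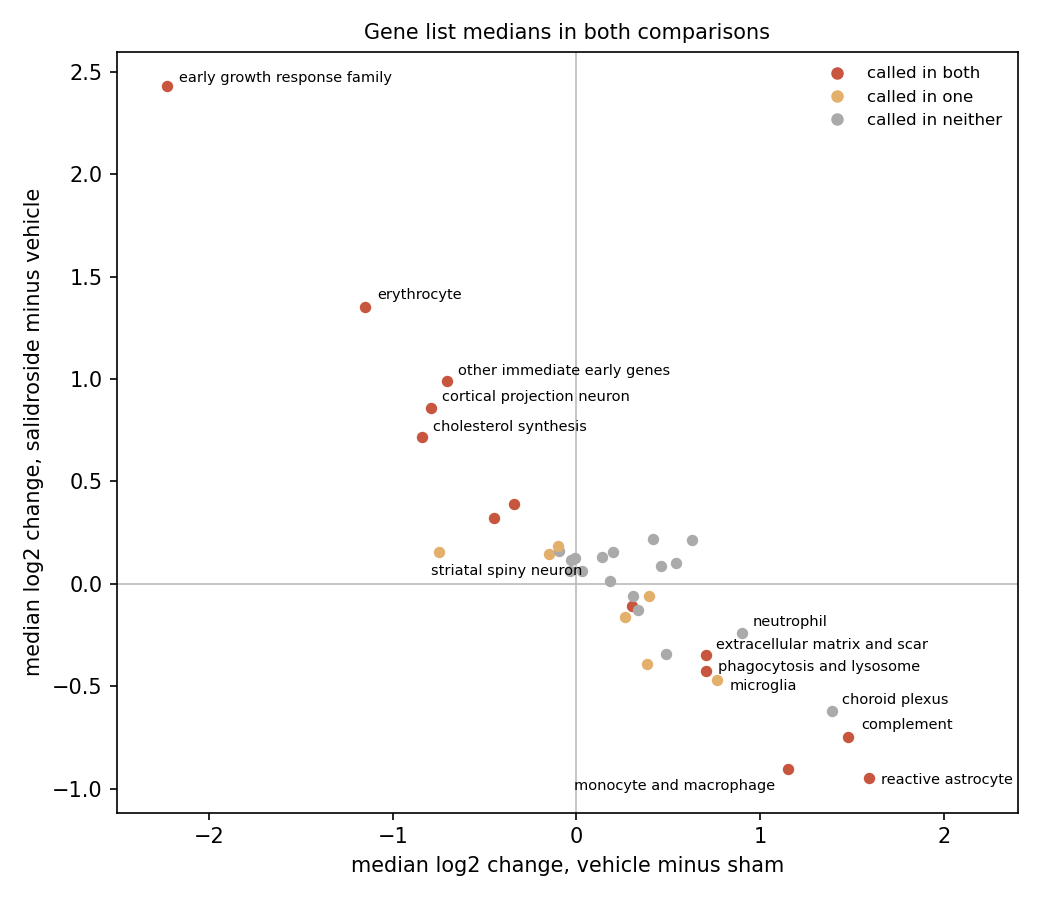
Median log2 change of each of the 37 gene lists, vehicle minus sham on the horizontal axis and salidroside minus vehicle on the vertical axis, coloured by whether camera called the list in both, one or neither comparison. The vehicle arrays enter both axes with opposite sign, which tilts the cloud downward to the right without any drug effect. The 13 lists called in both lie in the upper left or lower right. Under normexp correction the vertical value of macrophages, 1 of the 13, was 0.185, and that of microglia, called in 1 comparison, was 0.0777. Both lay below the median of all features there, 0.541.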

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

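These alternatives were chosen after seeing the data: normexp on the median spot signal, the title number block with 9 arrays, slide 1 arrays only, the list tests with slide or title number blocks or within slide 1, the list tests with slide as a random block, and the slide 3 MCAO arrays only. Normexp on the mean spot signal, planned at the outset, was not run, since that column was not used here. Single genes were followed under normexp, quantile and median scaling, the value table, the mean of probes, fits of 2 groups, the replicate block and without each array. No called gene among them reversed its direction there, but of the 35 named genes called between vehicle and sham 1, Cort, kept its call in all of these, and 242 of 553 values were no longer past the threshold. Of the 2 named genes called between salidroside and vehicle 0 kept the call in all (25 of 32 values not past it), and of the 8 between salidroside and sham 0 did (36 of 116). In this order, the counts of called features are given for vehicle against sham (592), salidroside against vehicle (3), salidroside against sham (267) and both MCAO groups against sham (756). Except where stated, the cause was not tested.

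Under normexp limma called 13, 0, 0 and 36 (for salidroside against vehicle 974 features had an unadjusted p under 0.05). Quantile normalization gave 1141, 7, 717 and 1309, and median scaling 924, 11, 638 and 1418. The deposited value table gave 1197, 17 and 586 for the first 3, and 462 of the 592 and 216 of the 267 calls were kept in it. The share of calls that were higher moved with the setting. Under quantile normalization it went from 39.5% to 51.9% for vehicle against sham and from 20.2% to 51.3% for salidroside against sham. For vehicle against sham it was 0% under normexp, 13.2% without sham replicate 3 and 15.2% without vehicle replicate 3. It was 56.4% without salidroside replicate 1. Without a filter the counts were 296, 0, 171 and 417 (1307 at an unadjusted p under 0.05 for salidroside against vehicle). With probes well above background on all 9 arrays 10 were called between salidroside and vehicle, and with the mean of probes 1.

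With only the 2 groups compared in the fit the counts were 329, 0, 114 and 1135 (1171 at an unadjusted p under 0.05 for salidroside against vehicle). For the first 3 this leaves fewer arrays for the spread, while the fourth joins the MCAO arrays into 1 group of the same 9 arrays. A trend with robust estimation gave 979 and 25 for the first 2, and array weights gave 2745, 11, 2287 and 5035. An adjusted p under 0.1 gave 2041, 12, 581 and 2300, by its looser threshold, and an unadjusted p under 0.05 with a log2 change of at least 1 gave 1768, 278, 1323 and 1410.

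Counts were lower with blocks than in the main fit. For salidroside against vehicle a block in 6 arrays cannot show its own effect on the count, since these arrays gave 0 without a block too. Without a block 1171 features had an unadjusted p under 0.05 there, fewer than with slide or title number as a block. The replicate number as a block, although it does not pair the arrays, gave 297, 0, 125 and 300 (1643 at an unadjusted p under 0.05 for salidroside against vehicle). Slide as a random block gave 279 for vehicle against sham and 345 for both MCAO groups against sham. A scan day block gave 114, 98 and 145 for the comparisons with sham, the same as leaving out sham replicate 3, since that array alone was scanned on its day. Between salidroside and vehicle limma called 0 with slide as a block in 6 arrays, 0 with the title number as a block in 6 arrays, 0 with it in 9 arrays and 0 within slide 1, and 2093, 2203, 1722 and 1376 had an unadjusted p under 0.05. With the slide 3 MCAO arrays only, limma called 0 against sham (2069 at an unadjusted p under 0.05).

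Leaving out 1 array gave 114 (without sham replicate 3) to 1071 (without salidroside replicate 1) for vehicle against sham, 0 (without any array but vehicle replicate 1) to 8 (without that array) for salidroside against vehicle, 90 (without salidroside replicate 3) to 1031 (without salidroside replicate 1) for salidroside against sham, and 145 (without sham replicate 3) to 2061 (without salidroside replicate 1) for both. For salidroside against vehicle, 1003 to 1666 features had an unadjusted p under 0.05 where 0 were called. The correlation between the 2 effects went from -0.678 (without vehicle replicate 2) to -0.311 (without salidroside replicate 1), and from -0.621 to -0.461 under the other alternatives.

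Of the list calls, 10 of the 17 between vehicle and sham and 10 of the 16 between salidroside and vehicle held in all camera settings run at the preset correlation. Normexp ended the calls of glutamatergic synapse, channel and macrophage genes between salidroside and vehicle. With an estimated correlation 0, 1 and 0 lists were called for vehicle against sham, salidroside against vehicle and salidroside against sham, and fry called 5, 5 and 0. For salidroside against sham, with 1 call, normexp gave 7, quantile normalization 0, median scaling 2, probes above background on all 9 arrays 2, the replicate block 2 and slide as a random block 0. Leaving out 1 array gave 11 (without vehicle replicate 3) to 21 lists for vehicle against sham, 15 to 20 for salidroside against vehicle and 0 (without salidroside replicate 3) to 2 (without salidroside replicate 2 or vehicle replicate 3) for salidroside against sham. Signal over background limited sham replicate 3 most, with 65.63% of probes well above background.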

Other observations

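The tests that weigh explanations for the activity and cholesterol genes and for the complement and astrocyte genes, and the test of slides for probes without an accession, were chosen after the result was seen, while the list tests themselves and leaving out each array had been chosen before.

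Choroid plexus genes varied widely within both MCAO groups. Their mean level against sham was 1.46, 0.993 and 3.95 on vehicle replicates 1 to 3 and -0.369, 1.26 and 2.4 on salidroside replicates 1 to 3. Ttr, the carrier protein that choroid plexus makes in bulk, had a scaled log2 signal of 6.42 on salidroside replicate 3, 4.302 on vehicle replicate 1 and 6.45 on vehicle replicate 3, and from -3.459 to -1.297 on the other 6 arrays. Otx2 had a log2 change of 5.352 between vehicle and sham (adjusted p = 0.177). Ttr and Otx2 were singled out after their values were seen.

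Brain region markers also differed within groups. The striatal list stood at 1.32 on sham replicate 1 and -0.6 and -0.716 on the other sham arrays, against the sham mean. The oligodendrocyte list stood at -0.611 on sham replicate 1, -0.755 on salidroside replicate 1 and 0.425 and 0.394 on the other salidroside arrays. The thalamic list stood at -0.719, 0.855 and 1.04 on the vehicle arrays. Hba-a1, chosen after its values were seen, had a log2 change of 1.224 between salidroside and vehicle (adjusted p = 0.34) and -1.058 between vehicle and sham (adjusted p = 0.0611).

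The lists of early growth response, other immediate early and cholesterol synthesis genes were called lower with vehicle than with salidroside, with 0 members past limma over all genes (1351 features at an unadjusted p under 0.05) and adjusted p of 0.0533, 0.0983 and 0.0178 with an estimated correlation. Shifts between slides do not account for it, since both groups had 2 arrays on slide 1 and 1 on slide 3, so such shifts cancel. Within slide 1, with 2 arrays per group, the smallest of the 3 list medians was 0.766 (camera adjusted p at most 0.000149). A loss of neurons of all kinds alike from the vehicle tissue would lower neuron markers about as much as the activity genes, whose median differed by 1.01. The neuron median differed by 0.187 (SD 0.109). These markers cannot exclude a loss of only some kinds of neuron. Less cortex would need cortical markers to differ as much as the early growth response genes (2.43), against 0.86 (SD 0.472). These SDs are over marker genes, not arrays. Over arrays the level of the cortical list had an SD of 0.37 with vehicle and 0.446 with salidroside. For the other immediate early genes less cortex cannot be told apart, since the cortical markers were lower by a similar amount between vehicle and sham (-0.789, SD 0.478 over genes). Cholesterol synthesis genes were not tested against these markers. Their medians, 0.718 between salidroside and vehicle and -0.838 between vehicle and sham, were close to the cortical ones, so less cortex stays open for them. A stress response in the vehicle animals is a candidate explanation that stays open, as 12 measured genes known to be induced by glucocorticoids, a list chosen after gene results were seen, had a median of 0.664 between vehicle and sham (camera p = 8.5e-05, 0.0488 with an estimated correlation) and -0.38 between salidroside and vehicle, although several also respond to injury. Of these genes only Sgk1 and Angptl4 passed limma between vehicle and sham (adjusted p = 0.0286 and 0.0389). None passed between salidroside and vehicle, where the smallest limma adjusted p was 0.668. The shared vehicle arrays also favour opposite signs. An effect of salidroside stays open as well.

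The lists of complement and reactive astrocyte genes were called lower with salidroside than with vehicle at the preset correlation (adjusted p = 0.321 and 0.198 with an estimated one), and that of antigen presentation was not called. Less injured tissue in the salidroside dissections would lower the linear signal over sham of all injury genes by the same share. It was 33% of the vehicle level for complement and reactive astrocyte genes and 52.6% for antigen presentation and cytokine genes, an excess of 0.25 (SD 0.259, n = 3) that lies within its spread, so dissection and a drug effect cannot be told apart. Choroid plexus levels ordered the MCAO arrays much as complement levels did (1.22, 0.884 and 1.89 on vehicle replicates 1 to 3 and 0.146, 0.375 and 1.32 on salidroside replicates 1 to 3). The median of reactive astrocyte genes without salidroside replicate 1 was -0.442, so that array alone does not account for it. Both groups had 2 arrays on slide 1 and 1 on slide 3, so a shift between slides cancels in this comparison. Within slide 1, with 2 arrays per group, the weaker of the 2 medians was -0.824 (camera adjusted p at most 6.17e-05). Even there the complement level of salidroside replicate 3 (1.32) lay above that of vehicle replicate 1 (1.22).

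Probes without an accession were called lower for the mean of both MCAO groups against sham more often than named genes, 5.98% against 0.572%. Dim probes alone do not account for it, since the share was above that of named genes in each of 4 bins of signal, 1.06%, 4.17%, 13.3% and 8.54% against 0.251%, 0.4%, 0.793% and 0.754%. Nor does sham replicate 3 alone, without which 2.54% were lower, against 0.121%. With slide as a random block 137 were lower, but sham and MCAO arrays shared no slide, so slides and ischemia cannot be told apart. What these probes measure was not analysed here.

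Arrays were also regrouped in all other ways. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Counting the real split, as many features were called in 1 of 10 for vehicle against sham (592, highest other 2), 2 of 10 for salidroside against vehicle (3, highest other 16) and 1 of 10 for salidroside against sham (267, highest other 0). As many lists were called in 2 of 10 (17, highest other 17), 2 of 10 (16, highest other 20) and 10 of 10 (1, highest other 10). The split with 16 features, several times the real count, set salidroside replicates 1 and 3 and vehicle replicate 1 against the rest. What that split reflects was not tested. Among the 4 splits that part all 3 pairs by title number, the real one called 3 features and the highest other 0, and 16 lists against 20. For both MCAO groups against sham, in a fit of 2 groups, 1 of 84 splits, the real one, called as many as the real 1135. That is the smallest share these splits can give, so chance is unlikely if arrays are exchangeable. They are not fully so, since MCAO and sham share no slide and MCAO arrays pair by title number, and 345 were called with slide as a random block in the fit of 3 groups. The highest other, 646, set sham replicate 1 and both arrays of slide 3 against the rest and shared 0 calls with the real split.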
